A study of Mus musculus with 4 samples.

How the data were processed

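ChIP-seq was done on organoids grown from a mouse colorectal tumour that had been induced with azoxymethane and dextran sulfate sodium (clone 3, passage 14). There was 1 library each for KMT9alpha, KMT9beta, H4K12me1 and input, sequenced on an Illumina HiSeq instrument. The treatment text names tamoxifen at 1 µM and vehicle without saying which was given to these libraries, and no genotype is stated, so no treatment was compared. The labels name both STAR and Bowtie2 for mapping to mm10, and their versions and settings are not given in the sources used here. The deposited peak lists give a position and a score for each peak, and the peak names begin with MACS. The version, threshold and control used by the authors for peak calling and the exact meaning of the score are not given in the sources used here. In the deposited lists the lowest score was 50, and 5011 KMT9alpha peaks (19.2%), 2 KMT9beta peaks and 5 H4K12me1 peaks had a score of 3100 or more. Scores were therefore used only to rank or compare peaks within 1 list. The depth of the libraries is unknown, so the sensitivity of the lists cannot be compared, and the input library is not analysed here.

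Peaks were checked for overlaps within a list, of which there were none, and those on chromosomes 1 to 19, X and Y were kept. This removed 81, 124 and 120 peaks on unplaced sequences for KMT9alpha, KMT9beta and H4K12me1. Genes were those of GENCODE M21 on GRCm38.p6, the assembly behind mm10. A promoter was 1 kb either side of any annotated start of a protein-coding gene. Peaks overlapped when they shared 1 bp or more. Each overlap and promoter share was set beside 100 random placements of the same intervals on the same chromosome outside assembly gaps of 50 bp or more. Midpoints were assigned in the order promoter, 5' UTR, coding exon, 3' UTR, non-coding exon, intron, intergenic. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only. With 1 library per antibody no p-value across peaks or genes was computed, and no paired analysis was possible because no sample has a partner in another condition.

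The comparisons, the gene lists, the rule for named genes and most other settings tried were fixed in advance. There were 15 lists: KMT9 subunits, intestinal stem cell, Wnt pathway, MYC and nucleolar ribosome biogenesis, cytosolic ribosomal proteins, cell cycle and DNA replication, enterocyte and colonocyte differentiation, goblet and other secretory cells, mitochondrial respiratory chain, p53 response and apoptosis, chromatin writers and erasers, immune cells, fibroblasts and endothelium, neurons and germ cells, and olfactory and vomeronasal receptors. The share of each list with a promoter peak was compared with 10000 random lists of the same size drawn from protein-coding genes and matched on 5 classes of promoter CpG observed to expected ratio. The percentile gives the position of the list among them, with random lists of equal count divided evenly above and below. Reactome sets of 15 to 200 genes came from the mouse collection in fgsea 1.28.0 (R 4.3.3), 748 in all, and were ranked by fold over the matched random mean. The named genes were the 10 with all 3 libraries at the promoter and the highest KMT9alpha score (ties by symbol), per list the pair of members with all 3 and the highest KMT9alpha score and up to 2 members with none of the 3 in alphabetical order, and N6amt1, Trmt112, Myc, Lgr5, Ctnnb1 and Apc. Some items that these rules pick are not reported here. Differences of median score have bootstrap intervals over peaks from 1000 resamples.

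After the lists had been seen, peaks outside promoters were counted in bins of 1 Mb and modelled by Poisson regression on GC content, its square, the logarithm of gene number and repeat share, fitted on the autosomes other than 5 and 19. The dense part of chromosome 5 was the run of bins where KMT9alpha peaks outside promoters exceeded this model most, by likelihood ratio. Promoter shares on chromosome 5, 19 and X were compared with genes of other autosomes in the same CpG class. The other settings changed the overlap rule, the score threshold, the number of peaks per list, the peak width, the random placement, the promoter window, the set of gene starts and the matching of random lists. Leaving out the dense part of chromosome 5, or chromosomes 5 and 19, and asking for all 3 at the same start of a gene, were added after seeing the data.

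The steps were tested on simulated data. Of 5000 simulated peaks planted to overlap in 40% of cases, 43.3% overlapped, which includes chance overlaps, and unrelated lists gave a fold of 1.03. Among unrelated lists of 25 genes 4.8% fell in the outer 5%, and 96% of lists drawn with odds of 6 were found above. A block with 4 times the modelled density was measured at 3.92 times. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.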

Results

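Chromatin of mouse colorectal tumour organoids was profiled by ChIP-seq with antibodies against KMT9alpha, KMT9beta and histone H4 monomethylated at lysine 12 (H4K12me1). KMT9alpha, the product of N6amt1, and KMT9beta, the product of Trmt112, form the methyltransferase KMT9, which is known to write H4K12me1. The organoids were grown from a tumour induced with azoxymethane and dextran sulfate sodium (clone 3, passage 14). Each antibody had 1 library, so no value below has a replicate check. An input library was sequenced as well and is not analysed here. The depth of the libraries is unknown. The lists held 26227 KMT9alpha peaks, 90473 KMT9beta peaks and 60409 H4K12me1 peaks, of which 26146, 90349 and 60289 lay on the assembled chromosomes of mm10 and were used. Median peak width was 831 bp for KMT9alpha, 992 bp for KMT9beta and 623 bp for H4K12me1, and the peaks covered 1.04%, 4.13% and 1.74% of the genome. All intervals given are exact binomial 95% intervals unless stated otherwise. They cover counting over peaks or genes in 1 library, and neighbouring peaks are not independent.

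The first comparison asked how far the subunits of the enzyme and its histone mark coincide. Most KMT9alpha peaks, 75.2% (74.7 to 75.8, 19670 of 26146), overlapped a KMT9beta peak, and 49.9% (49.3 to 50.5, 13047) overlapped an H4K12me1 peak. KMT9alpha peaks with both partners made up 45.3% (44.7 to 46.0, 11856). Myc, a growth-promoting transcription factor, Lgr5, a marker of intestinal stem cells, and the Wnt pathway genes Ctnnb1 and Apc each carried promoter peaks of all 3 libraries, although the highest KMT9alpha and H4K12me1 peaks of Myc and of Ctnnb1 did not overlap. Of the KMT9beta peaks, 33.6% (33.3 to 33.9) overlapped H4K12me1 and 20.7% (20.4 to 20.9) overlapped KMT9alpha. Of the H4K12me1 peaks, 56.1% (55.7 to 56.5) overlapped KMT9beta and 22.3% (22.0 to 22.6) overlapped KMT9alpha.

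H4K12me1 was present at 60.3% (59.6 to 61.0) of the KMT9alpha peaks that also had KMT9beta and at 18.4% (17.5 to 19.4) of those without it. Likewise, 62.7% (62.0 to 63.4) of KMT9beta peaks with KMT9alpha had H4K12me1, against 26.0% (25.6 to 26.3) of KMT9beta peaks without KMT9alpha. At promoters, within 1 kb of an annotated start of a protein-coding gene, 91.3% of KMT9alpha peaks overlapped KMT9beta and 60.5% overlapped H4K12me1. Away from promoters these shares were 61.8% and 41.1%. Randomly placed KMT9alpha peaks overlapped KMT9beta in 9.32% of cases (8.87 to 9.77 over 100 placements) and H4K12me1 in 5.33% (4.83 to 5.68), which puts the observed shares 8.07-fold and 9.37-fold above random placement. The share with both partners was 13.7-fold above its random mean of 3.31%. When the placements kept each peak's distance to the nearest gene start, the folds were 2.09 for KMT9beta, 2.33 for H4K12me1 and 2.42 for both. With the same number of peaks taken from each list, 26.7% of KMT9alpha peaks had both partners and 48.9% of KMT9beta peaks overlapped KMT9alpha. With peaks outside promoters only, 10.6% of KMT9beta peaks and 11.4% of H4K12me1 peaks overlapped KMT9alpha.

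**Figure D1:**
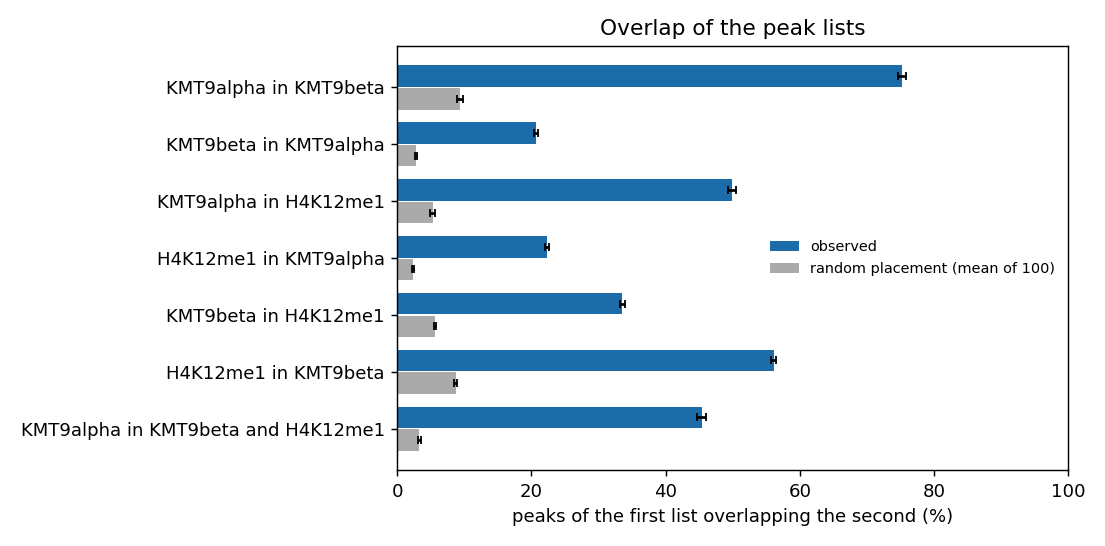
Bars give the percentage of peaks of the first-named list that overlap the second, with exact 95% intervals, and grey marks give the mean and range of 100 random placements. Every observed share, from 20.7% to 75.2%, is above its random range.

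The next comparison asked where in the genome the peaks lie. KMT9alpha was the most promoter-centred of the 3 lists: 45.4% (44.8 to 46.0) of its peaks overlapped a promoter, against 18.8% (18.5 to 19.04) for KMT9beta and 19.4% (19.1 to 19.7) for H4K12me1. Random placement gave 4.001%, 4.203% and 3.71%, so the shares were 11.4-fold, 4.47-fold and 5.23-fold above it. With the KMT9alpha peaks split into 4 equal classes by score, 94.1% of the highest class and 11.5% of the lowest were at promoters. The same classes held 44.1% and 6.48% promoter peaks in the KMT9beta list and 32.2% and 15.7% in the H4K12me1 list. By midpoint, introns held 41.4% of KMT9beta peaks, 40.9% of H4K12me1 peaks and 26.4% of KMT9alpha peaks, and introns make up 40.01% of the genome. The promoter share of KMT9beta was 40.8% with the same number of peaks per list, and with promoters widened to 5 kb the shares of KMT9beta and H4K12me1 were 32.1% and 33.4%. The promoter share of KMT9alpha was 76.9% among peaks at or above its median score.

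Promoters of protein-coding genes were then compared to see which genes carry the subunits and the mark. Of 21853 genes, 11854 (54.2%) had a KMT9alpha promoter peak, 14219 (65.1%) a KMT9beta peak and 9820 (44.9%) an H4K12me1 peak. All 3 were present at 7747 genes (35.5%), where 3466 would be reached if the gene sets were independent and 6117 if they were independent within 5 classes of promoter CpG content. The peaks may lie at different annotated starts of a gene, and at 7557 genes all 3 lay at the same start. None of the 3 was present at 6458 genes. The share of genes with all 3 was 4.62% in the class with the lowest CpG ratio and 68.4% in the class with the highest. Both subunits without H4K12me1 were found at 3390 genes, and KMT9beta with H4K12me1 but no KMT9alpha at 1463. H4K12me1 was found at 6315 promoters and all 3 at 4856 with the same number of peaks per list. Among peaks at or above the median score all 3 were found at 5038.

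The genes with all 3 and the highest KMT9alpha scores were Fadd, an adaptor of death receptors, the histone genes Hist1h3a and Hist1h4a, Nmrk1 and Ostf1, Parp6, Rab34, Anxa2, the zinc transporter gene Slc30a3 and Uso1, which acts in vesicle transport. Their scores, from 3228.29 to 3233.06, lie near a ceiling of the scale, and 3949 genes with all 3 reached 3100 or more, so the order among them carries little information. Fadd (chromosome 7, 144577318 to 144582463) had a KMT9alpha peak at 144581312 to 144582941 with a score of 3233.06, a KMT9beta peak with a score of 455.33 and an H4K12me1 peak with a score of 164.02. Hist1h3a and Hist1h4a shared 1 KMT9alpha peak (chromosome 13, 23760449 to 23762448), and how reads were assigned among histone gene copies is not given in the sources used here. Nmrk1 and Ostf1 share a bidirectional promoter on chromosome 19 and the same peak of each library. Parp6 had scores of 3230.05, 58.94 and 156.66 for KMT9alpha, KMT9beta and H4K12me1, and Rab34 had 3230.05, 177.51 and 53.08. Slc30a3 lies in the peak-dense first part of chromosome 5 described further on.

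The genes that encode the enzyme both carried the subunits at their promoters. Trmt112 (chromosome 19, 6909698 to 6911049), which shares its promoter with Prdx5, carried all 3, with scores of 3100 for KMT9alpha, 750.74 for KMT9beta and 185.17 for H4K12me1, on a chromosome where H4K12me1 promoter peaks are denser than elsewhere, as given further on. N6amt1 (chromosome 16, 87354185 to 87368742) carried KMT9alpha at 87353936 to 87354721 with a score of 1968.94 and KMT9beta with a score of 83.17, and no H4K12me1 peak was called at its promoter, while 1 was called within the gene. Myc (chromosome 15, 61985391 to 61990374) had scores of 2365.21, 252.61 and 125.38 for KMT9alpha, KMT9beta and H4K12me1. Lgr5 (chromosome 10, 115450311 to 115587780) had 1362.05, 368.52 and 68.13, Ctnnb1 had 3100, 494.64 and 99.15, and Apc had 3100, 216.98 and 98.45.

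Gene lists chosen for the tissue and for the study's subject of growth and stemness were compared with random lists of the same size and promoter CpG content. Genes of chromatin writers and erasers stood highest: 22 of 25 (88.0%, 68.8 to 97.45) carried all 3, against 58.6% in the random lists (percentile 99.95), among them the acetyltransferase gene Crebbp and the DNA methyltransferase gene Dnmt1. When the same number of peaks was taken from each list, their share was 52.0% (percentile 91.0, inside the central 95% of random lists), and Wnt pathway genes (57.5%, percentile 99.33) and intestinal stem cell genes (52.0%, percentile 98.1) were the lists above it. Intestinal stem cell genes carried all 3 at 17 of 25 promoters (68.0%, 46.5 to 85.1), including Lgr5, the Wnt target Axin2 and Cdca7, against 50.7% (percentile 97.2, inside the central 95% of random lists), and 13 of these 25 had all 3 at the same start (52.0%, percentile 59.7). KMT9alpha, with or without the others, was present at 22 of these 25 promoters (percentile 98.2), and the stem cell genes Aldh1a1 and Rnf43 had no promoter peak. Wnt pathway genes had all 3 at 29 of 40 promoters (72.5%, 56.1 to 85.4), including Apc and Axin1, against 58.9% (percentile 96.4), and their H4K12me1 share, 33 of 40, was at percentile 99.2. The Wnt receptor gene Fzd8 and Porcn, which is on chromosome X, had none.

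Genes of growth and cell division carried KMT9alpha at nearly every promoter, but so did respiratory chain and p53 genes, given below, and chromatin genes (24 of 25, percentile 98.5). The random lists were matched on promoter CpG content only and not on how active the genes are. All 25 genes of MYC and nucleolar ribosome biogenesis had KMT9alpha (percentile 99.9), but 11 of 25 had H4K12me1, against 63.1% in the random lists (percentile 2.46). That percentile is barely below the limit of 2.5. Dkc1, a member without H4K12me1, is on chromosome X, where few promoters had the mark, as given further on. The random lists were not matched on chromosome, and the share was not computed without Dkc1. All 3 were present at 11 of these 25 genes (44.0%, 24.4 to 65.1, percentile 11.9), including Bop1, whose promoter is shared with Hsf1, and Cad, which lies in the dense part of chromosome 5. Cytosolic ribosomal protein genes carried KMT9alpha and KMT9beta at 25 of 25 promoters (percentiles 99.9 and 98.4) and all 3 at 17 (68.0%, percentile 89.9), including Rpl10a and Rpl11. Cell cycle and DNA replication genes had KMT9alpha at 29 of 30 promoters (percentile 97.8) and all 3 at 19 (63.3%, percentile 76.9), including the cyclin gene Ccnd1 and the mitotic kinase gene Aurka, which shares its promoter with Cstf1. Bub1, a spindle checkpoint gene, had none. Respiratory chain genes had KMT9alpha at 25 of 25 (percentile 99.51) and all 3 at 17 (68.0%, percentile 88.5), including Atp5a1 and Cox4i1, which share their promoters with Haus1 and with Gm27021 and Emc8. Genes of the p53 response and apoptosis had KMT9alpha at 25 of 25 (percentile 100), KMT9beta at 24 (percentile 99.02) and all 3 at 15 (60.0%, percentile 84.0), including Bax and Apaf1, which shares its promoter with Ikbip.

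Lists of differentiated cells of the gut stayed inside the central 95% of random lists for each library and for all 3. H4K12me1 was present at 10 of 25 enterocyte and colonocyte genes (40%, against 29.4%, percentile 89.8) and at 12 of 25 genes of goblet and other secretory cells (48.0%, against 36.0%, percentile 90.8). For enterocytes and colonocytes 5 of 25 genes carried all 3 (20%, 6.83 to 40.7, against 19.6%): Vil1, Car2, Slc5a1, Klf4 and Hnf4a. Of these, Vil1, Slc5a1 and Hnf4a were named after their values were seen. Car1 and Car4, carbonic anhydrase genes, had none. For goblet and other secretory cells 4 of 25 carried all 3 (16.0%, 4.54 to 36.1, against 24.6%, percentile 13.7): the transcription factor genes Atoh1, Insm1 and Gfi1, and Chgb, the last pair named after their values were seen. Ang4 and Clca1 had none.

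Lists of genes of other cell types were compared in the same way, and promoter peaks at them do not show which cells the culture held. No gene of the 25 immune genes carried all 3 (0%, upper limit 13.7%, against 11.4%, percentile 2.07), and Adgre1 and Cd3e had no promoter peak of any library. With equal peak numbers the immune list, still at 0, was at percentile 8.39, inside the central 95% of random lists. Among fibroblast and endothelial genes 5 of 25 carried all 3 (20%, against 27.8%, percentile 16.9): Fn1, Flt1, Pdgfra, Vim and Esam, the last 3 named after their values were seen. KMT9alpha was present at 7 of these 25 (percentile 1.92) and KMT9beta at 17 (68.0%, against 58.5%, percentile 86.4), and the matrix genes Col3a1 and Dcn had none. Neuron and germ cell genes carried KMT9alpha at 6 of 25 promoters against 51.0% in the random lists (percentile 0.04) and H4K12me1 at 17 of 25 against 43.7% (percentile 99.4). The germ cell gene Dazl carried all 3, with scores of 648.23, 125.8 and 255.41 for KMT9alpha, KMT9beta and H4K12me1. Gria1, a receptor gene of neurons, had none. Olfactory and vomeronasal receptor genes carried all 3 at 3 of 1465 promoters (0.205%, 0.0423 to 0.597, against 5.68%): Vmn1r4, which shares its promoter with Nt5c3, Olfr317 and Olfr641, the last named after its values were seen. At Olfr317 the KMT9alpha and H4K12me1 peaks lay at different starts. Olfr1 and Olfr10 had none. The list of KMT9 subunits, Trmt112 and N6amt1, is too short for a comparison.

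Over 15 lists and 4 measures (each library and all 3) 60 comparisons were made, of which 3 would lie in the outer 5% by chance. There were 13 above and 8 below, and lists that share a CpG class or a library are not independent of each other. With the same number of peaks per list the shares of respiratory chain, p53 and fibroblast and endothelial genes with all 3 were 32.0%, 36.0% and 4.0%.

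**Figure D2:**
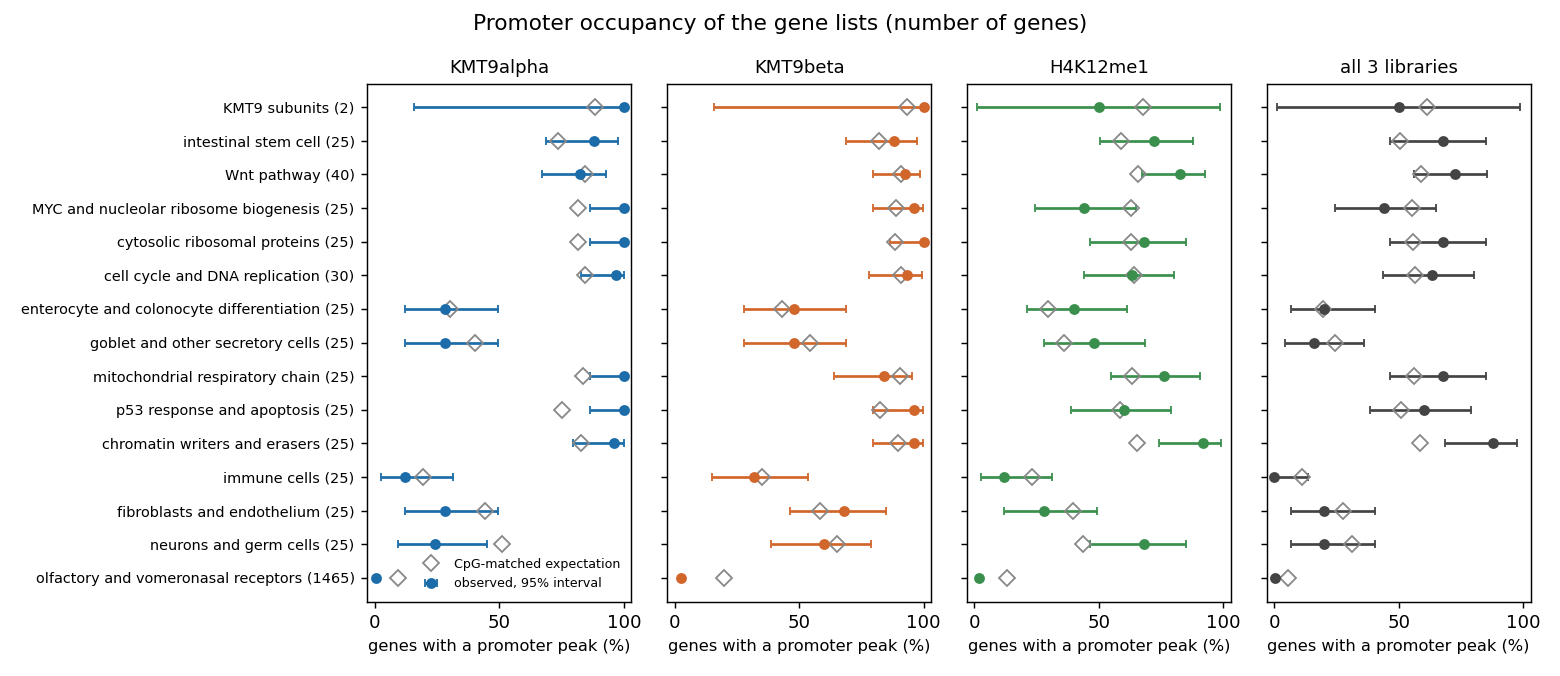
Points give the percentage of genes of each list with a promoter peak of KMT9alpha, KMT9beta, H4K12me1 or all 3, with exact 95% intervals, and open diamonds give the mean of random lists matched on promoter CpG content. Chromatin genes stand at 88.0% for all 3 against 58.6%, and neuron and germ cell genes stand below the diamonds for KMT9alpha and above them for H4K12me1.

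Promoters with all 3 were also counted over 748 Reactome pathways. Glycolysis had all 3 at 16 of 30 genes (53.3%, against 29.6%, 1.80-fold, percentile 99.8) and gluconeogenesis at 19 of 33 (57.6%, 1.67-fold, percentile 99.9). Other sets with high folds were acyl chain remodelling of PS (6 of 15, 1.85-fold), zinc transporters (11 of 17, 1.73-fold), PD-1 signaling (5 of 16, 1.73-fold), CD28 dependent PI3K Akt signaling (10 of 15, 1.62-fold), amino acid synthesis and interconversion (12 of 16, 1.61-fold), VEGFR2 mediated vascular permeability (17 of 22, 1.61-fold) and energy dependent regulation of mTOR by LKB1-AMPK (16 of 19, 1.60-fold). Of the sets named, acyl chain remodelling of PS (percentile 97.04), PD-1 signaling (91.4), CD28 dependent PI3K Akt signaling (98.7), zinc transporters (99.4) and amino acid synthesis (99.4) lay inside the central 99% of random lists. At the other end, 9 sets had no gene with all 3, so their order is that of their names. The 5 taken were xenobiotics (0 of 41), synthesis of epoxy and dihydroxyeicosatrienoic acids (0 of 20), synthesis of hydroxyeicosatetraenoic acids (0 of 26), miscellaneous substrates (0 of 16) and ligand-gated ion channel transport (0 of 20, against 27.4%, percentile 0.065). In all, 61 sets were above and 8 below the central 99% of random lists, where chance gives 3.74 on each side, and many sets share genes. With 9 sets at 0 and 8 below, a count of 0 does not by itself place a set below. There were 29 above and 2 below with the same number of peaks per list, and with random lists not matched on CpG content 300 were above and 31 below.

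The last planned comparison asked whether KMT9alpha peaks that carry the mark are the stronger ones. The median score of KMT9alpha peaks was 630.21 with H4K12me1 (13047 peaks) and 246.49 without it (13099 peaks), a difference of 383.72 (bootstrap 95% interval 341 to 425 over peaks). KMT9beta peaks had medians of 135.52 with H4K12me1 and 76.12 without. KMT9alpha peaks had medians of 586.42 with KMT9beta and 205.65 without. The difference of KMT9alpha scores with and without KMT9beta was 1986.16 at promoters and 16.3 elsewhere. The difference for KMT9alpha and H4K12me1 was 1428.4 at promoters and 5.02 elsewhere (2.08 to 7.62). The peaks elsewhere include 1800 from the dense part of chromosome 5 described further on. Their median score was 112.9, against 218.2 for KMT9alpha peaks outside promoters on other autosomes. Of all KMT9alpha peaks in that part 69.8% overlapped H4K12me1, against 47.4% on other autosomes. Weak peaks with the mark there may lower the difference elsewhere, which was not computed without this part. Averaged over 4 classes of peak width the difference for KMT9alpha and H4K12me1 was -25.1, the opposite direction.

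Peak density also differed between parts of the genome, which was examined only after the lists had been seen. The stretch of chromosome 5 with the strongest excess of KMT9alpha peaks over the model given next ran from 3 to 33 Mb. Its ratios are therefore partly fixed by that choice, most of all for KMT9alpha. This first part of chromosome 5 held 7.70% of all KMT9alpha peaks. Outside promoters its peaks were 18.4 times the number modelled from GC content, gene number and repeats for KMT9alpha, 3.22 times for KMT9beta and 6.04 times for H4K12me1. The ratios on chromosome 19 were 3.69, 2.49 and 3.82, those on the rest of chromosome 5 were 1.06, 1.09 and 1.08, and no other autosome as a whole exceeded 1.502. The excess was not even over the dense part and not limited to it. In the 1-Mb bins starting at 11000001, 12000001 and 13000001 of chromosome 5, where few peaks are modelled, KMT9alpha had 1, 1 and 0 peaks outside promoters, against 0.974, 0.491 and 0.491 modelled. In the same bins KMT9beta had 13, 1 and 8, against 4.501, 2.59 and 2.71, and H4K12me1 had 6, 3 and 3, against 2.704, 1.51 and 1.57. Elsewhere on chromosome 5, the bin starting at 99000001 held 99, 145 and 153 peaks of KMT9alpha, KMT9beta and H4K12me1 per Mb, against 3.81, 24.8 and 15.1 modelled, and the bin before it held 25, 36 and 36, against 1.81, 10.6 and 6.35. More genes carried H4K12me1 at the promoter in the dense part of chromosome 5 (74.8%, 68.5 to 80.3) and on chromosome 19 (72.3%, 68.9 to 75.6) than the 46.1% and 46.4% found at autosomal genes of the same CpG content. On chromosome X the shares were lower: 289 of 948 genes carried KMT9alpha (30.5%, 27.6 to 33.5, against 43.9%), 64 carried KMT9beta (6.75%, 5.24 to 8.54, against 59.7%) and 4 carried H4K12me1 (0.422%, 0.115 to 1.08, against 39.3%). These 4, named after their values were seen, were F8a, Gk, Gm21887 and Asmt. Without the dense part of chromosome 5, 44.3% of KMT9alpha peaks had both partners, and without chromosomes 5 and 19 the share was 42.9%.

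**Figure D3:**
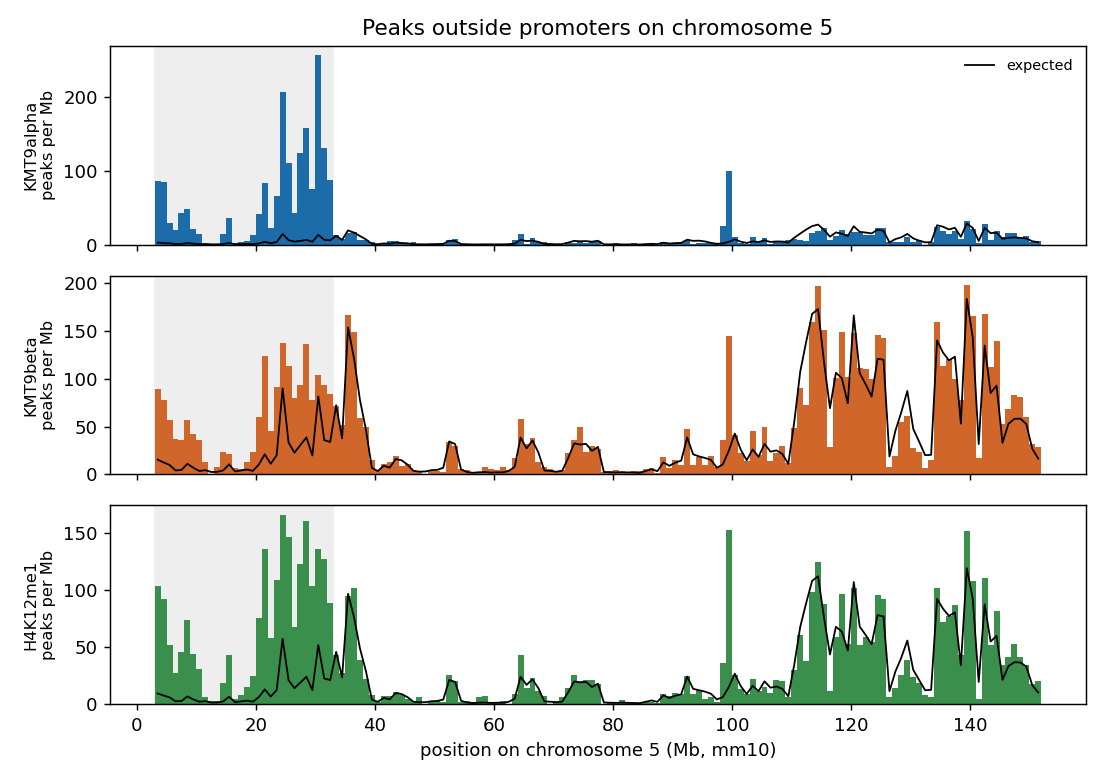
Peaks outside promoters per Mb along chromosome 5 for KMT9alpha, KMT9beta and H4K12me1, with a line for the number modelled from GC content, gene number and repeats and grey shading from 3 to 33 Mb. The shaded part, chosen for its KMT9alpha excess over the model, holds 18.4, 3.22 and 6.04 times the modelled number of peaks.

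**Figure D4:**
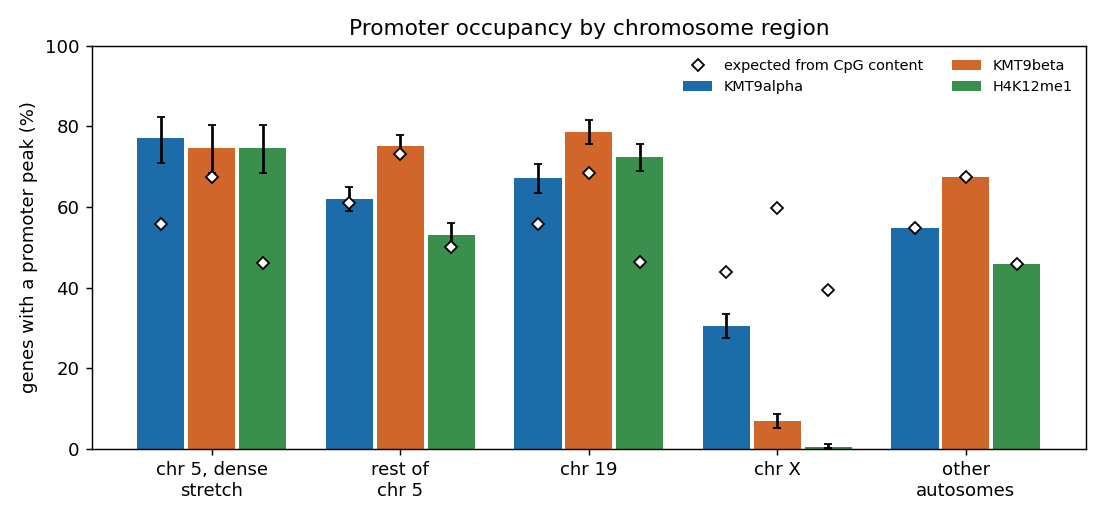
Bars give the percentage of protein-coding genes with a promoter peak in the dense part of chromosome 5, on chromosome 19, on chromosome X and elsewhere, with exact 95% intervals, and diamonds give the share at genes of other autosomes with the same CpG content. H4K12me1 on chromosome X stands at 0.422% against 39.3%.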

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

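No test was run on the values given here, and the comparison of densities was chosen after the counts had been seen. Peaks on unplaced or unlocalized sequences of the assembly, which no comparison used, numbered 81 for KMT9alpha, 124 for KMT9beta and 120 for H4K12me1. They stand out only as signal outside the chromosomes compared. Their density over the 44 sequences was 15.2, 23.2 and 22.5 peaks per Mb, against 9.88, 34.1 and 22.8 on the chromosomes.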

How the results depend on the processing

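The settings without the dense part of chromosome 5 and without chromosomes 5 and 19, and the count of all 3 at the same start of a gene, were chosen after seeing the data. Under the settings fixed before the data were examined 109 values stayed the same, 107 moved and 1 reversed, and under the added ones 41 stayed the same and 19 moved. The folds of overlap over random placement ranged from 1.56 to 27.4 over 9 settings, so each stayed above 1. A share counts as moved when it left its 95% interval, which is narrow in lists this long. No depth is known, so no limit from depth can be given.

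The reversed value was the score difference of KMT9alpha peaks with and without H4K12me1, which was 383.72 over all peaks and -25.1 within 4 classes of peak width. It was 1428.4 at promoters and 5.02 outside them, where the dense part of chromosome 5 was included. The cause was not tested.

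The overlap shares are given here for KMT9alpha in KMT9beta, KMT9alpha in H4K12me1, KMT9beta in H4K12me1 and KMT9alpha in both, in this order. They were 73.0%, 45.8%, 30.9% and 41.4% when at least 50% of the shorter peak had to be covered, 72.7%, 40.8%, 23.5% and 36.6% when the midpoint had to lie inside the other peak, and 59.9%, 41.0%, 26.8% and 31.2% with all peaks set to 500 bp. These rules count fewer overlaps by construction, as fewer bases can meet. For peaks at or above the median score of each list (13073, 45180 and 30167 peaks, fewer by construction) the shares were 83.8%, 43.3%, 31.7% and 41.1%. With the same number of peaks per list they were 53.6%, 33.4%, 39.8% and 26.7%. With peaks outside promoters only they were 58.6%, 39.8%, 28.2% and 31.8%. The last 3 shares were 48.2%, 32.8% and 44.3% without the dense part of chromosome 5 and 46.7%, 31.3% and 42.9% without chromosomes 5 and 19. The cause was not tested for the score, number, promoter and chromosome settings.

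The promoter shares of KMT9alpha, KMT9beta and H4K12me1 were 43.7%, 16.9% and 16.7% with a window of 500 bp, 55.2%, 32.1% and 33.4% with 5 kb, and 39.5%, 14.6% and 15.1% with the 5' end of each gene only, where the window or the number of starts changes them by construction. At or above the median score they were 76.9%, 29.7% and 24.0%. With the same number of peaks those of KMT9beta and H4K12me1 were 40.8% and 25.6%. Without the dense part of chromosome 5 those of KMT9alpha and H4K12me1 were 48.3% and 19.8%, and without chromosomes 5 and 19 the 3 shares were 50.2%, 19.7% and 20.7%. The cause was not tested for these last settings. Genes with all 3 numbered 5038 at or above the median score and 4856 with the same number of peaks, where H4K12me1 had 6315 genes. Fewer peaks were counted there by construction.

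With the same number of peaks 2 lists were above and 1 below the central 95% of random lists, against 1 and 2 in the main setting, and the shares with all 3 were 32.0% for respiratory chain, 36.0% for p53, 52.0% for chromatin and 4.0% for fibroblast and endothelial genes. The 2 lists above were intestinal stem cell (percentile 98.1) and Wnt pathway (99.33), and the 1 below was olfactory and vomeronasal receptors. In this setting 29 Reactome sets were above and 2 below. With unmatched random lists 7 lists, 300 sets above and 31 sets below were counted. With the 5 kb window 3 lists were above (intestinal stem cell, cytosolic ribosomal proteins and chromatin), and 0.887% of olfactory and vomeronasal receptor genes had all 3. With a peak anywhere in the gene or promoter 8 lists were above and 4 below (enterocyte, immune, neuron and germ cell, olfactory and vomeronasal), and the shares were 100% for KMT9 subunits, 68.0% for MYC and nucleolar, 83.3% for cell cycle and 80.0% for p53 genes. With all 3 at the same start of a gene 2 lists were above (chromatin and Wnt pathway, percentile 97.58) and 1 below (olfactory and vomeronasal), with the immune list at percentile 2.51. The cause was not tested for these lists.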

Other observations

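The tests in this part were chosen only after the result was seen, chromosome 19 taken alone included, except the density of peaks low in repeats over both dense regions together. Among promoters with both subunits but no H4K12me1 peak (3390 genes), assembly of the pre-replicative complex had 33 of 64 genes (51.6%, against 21.6% in CpG-matched random lists, percentile 100), and ribosomal scanning and start codon recognition had 28 of 56 (50.0%, against 22.4%, percentile 100). The fixed lists nearest to these sets by name stayed inside the central 95% of random lists: cell cycle and DNA replication genes with 9 of 30 (30%, against 24.2%, percentile 77.1) and cytosolic ribosomal protein genes with 8 of 25 (32.0%, against 22.96%, percentile 85.5). The members of the sets are not listed here, so which kinds of genes make up their counts is not shown. Of the MYC and nucleolar list 13 of 25 genes were in this class (percentile 99.9), among them Npm1, Nop58, Gnl3 and Polr1a, which restates its high share for KMT9alpha and low share for H4K12me1. Of the Wnt pathway list 4 of 40 were (Csnk1a1, Tcf7l1, Pygo2 and Wls, named after their values were seen, against 22.8%, percentile 2.02). The neuron and germ cell list had 0 of 25 (percentile 0.635). The chromatin list had 1 of 25, Kdm6a on chromosome X (percentile 0.94). The low counts of the Wnt pathway and chromatin lists restate their high shares for H4K12me1 (percentiles 99.2 and 99.9). That of the neuron and germ cell list restates its low share for KMT9alpha (percentile 0.04) and high share for H4K12me1 (percentile 99.4). Over 748 Reactome sets 112 were above and 23 below the central 99% of random lists for this class, where 7.48 are reached by chance on both sides together.

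Among promoters with KMT9beta and H4K12me1 but no KMT9alpha peak (1463 genes), the neurotransmitter release cycle had 13 of 44 genes (29.5%, against 7.42%, percentile 100), and G alpha s signalling events, which act downstream of many hormone receptors, had 27 of 97 (27.8%, against 8.23%, percentile 100). For this class 22 sets were above and 16 below. Intestinal stem cell, cell cycle, ribosomal protein and respiratory chain genes had 0 members in it, which is near chance at their sizes (percentiles 10.3, 9.38, 11.9 and 11.7). Goblet and other secretory genes had 5 of 25 (percentile 97.6): Muc2, Tff3, Spdef, Chga and Pou2f3, named after their values were seen.

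The dense peaks in the first part of chromosome 5 and on chromosome 19 appeared in all 3 libraries. GC content, gene number and repeat share as modelled left a lowest ratio of 2.49, above the highest of the other autosomes, 1.502. The part of chromosome 5 was chosen for its KMT9alpha excess over this model, which was fitted on autosomes other than 5 and 19. The comparison could thus hardly come out otherwise. It shows only that the model left an excess there and does not decide on these causes. For repeats and ambiguous mapping, the test set in advance asked for the lowest density ratio of peaks under 10% repeat sequence over both regions, which was 0.799, for KMT9beta on chromosome 5, where KMT9alpha had 4.67 and H4K12me1 1.553, so repeats stay open there, mainly for KMT9beta. On chromosome 19, split off after that outcome, the lowest was 1.96, which argues against repeats as the whole cause of the dense peaks. These ratios count promoter peaks and are not adjusted for gene number or GC content, so a part played by repeats is not excluded. Extra copies of these regions in the clone may raise both peaks and scores. The median score of CpG-rich promoters was at least 1.65 times that of other autosomes in KMT9beta and H4K12me1. KMT9alpha was at its ceiling there (median 3100 in each region). Its median over all promoter peaks was lower in these regions (788.45 on chromosome 5 and 1670.75 on chromosome 19, against 2183.06). That median covers called peaks only, and more genes had a KMT9alpha promoter peak there than CpG-matched autosomal genes, so it cannot decide. The ends that fitted best were 33 Mb for KMT9alpha and H4K12me1 and 30 Mb for KMT9beta. KMT9beta still exceeded the model in the bins starting at 31000001 and 32000001 (94 and 84 peaks outside promoters, against 35.9 and 34.0). In the bin at 33000001 it did not (72, against 72.5), so the fitted ends cannot decide either. As the input was not used, extra copies cannot be told apart from other causes. No biological explanation was tested beyond this, since the design has no second clone.

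Chromosome X had few promoters with KMT9beta or H4K12me1. CpG content is argued against, as the most CpG-rich X genes reached at most 0.253 of the autosomal share, and so is removal of all X reads for KMT9beta, which had 55 X peaks low in repeats, while H4K12me1 had 7, too few to decide. A loss of part of the X reads was not tested for either library. Fewer copies of X with a fixed score threshold may thin weaker lists most, and KMT9alpha kept 64.7 times as large a share of its expected X promoters as H4K12me1. If a missing copy were to halve scores, 173 genes would still pass for H4K12me1 and 434 for KMT9beta, far more than the 4 and 64 observed, but how scores change with copies is unknown, so this and a difference in the mark cannot be told apart. The hypothesis that H4K12me1 at X promoters follows KMT9alpha as on autosomes could not be decided: the ratio of observed to expected genes was 0.0216 (4 of 289, against 186), but only 4 X genes had the mark at all, which fixed this outcome.

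Promoters with KMT9beta and H4K12me1 but no KMT9alpha left 2 explanations open. Weak signal under the KMT9alpha threshold may account for part of them. Among CpG-rich promoters their median H4K12me1 score was 0.795 and their median KMT9beta score 0.559 of that at promoters with all 3. In each pair of lists compared, however, promoter peaks without the partner had lower median scores (for H4K12me1 77.06 without KMT9beta and 98.05 with it). Lower scores may thus appear under either explanation and cannot decide between them. A gene class with H4K12me1 apart from KMT9alpha may account for others, but this cannot be told apart here: 9 of 25 neuron and germ cell genes were in the class (Snap25, Gad2, Camk2a, Tubb3, Ddx4, Sycp1, Sycp3, Prm1 and Prm2, all named after their values were seen, against 8.66%, percentile 99.99). That list had already been seen to be low for KMT9alpha and high for H4K12me1, so its excess restates the pattern. With the same number of peaks per list Gad2, Tubb3 and Prm1 were in the class (3 genes, percentile 98.3).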
